A study of Mus musculus with 3 samples.

How the data were processed

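PolyA-selected RNA of mouse regulatory T cells was sequenced in 3 libraries, which form 1 group. The group and the replicate numbers were taken from the labels, which give 1 biological replicate with technical replicates 1 to 3, 1 donor and 1 biosample, so the libraries were never treated as separate animals. Per the labels, fragments were made by shearing on a Covaris instrument. The aligner and the counter with their versions are not given in the sources used here.

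For each library the authors deposited a gene table and a transcript table with expected counts, TPM and FPKM, where TPM and FPKM are scaled for transcript length and depth. The column names are those that RSEM writes, and effective length was length minus 49, which is what a model of single reads of 50 bases gives. The assembly is mm10 and the annotation GENCODE M21, per the deposited text beside the files. The transcript table also holds a percent of its gene's TPM for each transcript, per the file headers. The gene table had 81881 rows, of which 55536 are annotated genes, 26248 are tRNA entries, 96 are ERCC spike-in entries and 1 is phiX174, a sequencing control. The latter 3 kinds stayed out of tests and lists. A second gene table deposited for each library holds whole-number counts per gene for GENCODE M4, also from an mm10 alignment, per the deposited text. The counting rule of that table is not given in the sources used here. Depth was 20995859, 18455925 and 17535096 expected counts in the first table and 6339932, 5775622 and 5056487 counts in the second.

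Gene names, biotypes and coordinates came from the GENCODE M21 annotation, the release of the first table, and positions are 1-based on mm10. Expected counts were rounded to whole numbers before tests. Genes with a mean count of at least 10 were tested by a Pearson chi-square test against Poisson sampling, with library sizes scaled by edgeR's TMM factors, 2 degrees of freedom and a Benjamini-Hochberg adjusted threshold of 0.05. The coefficient of variation beyond counting is the square root of edgeR's common dispersion in an intercept-only design. Levels are TPM as deposited, and a gene counted as detected at 1 TPM or more in each library. Ratios of gene pairs are on the log2(TPM + 1) scale, which understates ratios of low genes. For each of 31 gene lists with 323 genes, the median of the mean log2(TPM + 1) was placed among 10000 random lists of the same size drawn from protein-coding genes (seed 1). A list of another cell type was also given as its median TPM in percent of that of the T cell identity list. The floor for genes at 0 is 3 counts. Effective length was averaged over the libraries for floors and for trends with length. Floors cover counting error only, since reads without molecular identifiers are not independent molecules.

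Lists, pairs, isoform genes, tests and alternatives were fixed before the data were examined, except where said otherwise. The top 2.5% as the limit for list levels was not among the choices fixed then. The named genes follow a rule. It takes the 4 highest members of each list, members under 1 TPM in any library where there are 4 or fewer of them (not for cytokines or other cell types), and a fixed set of 21 genes from Foxp3 to Lyz2. It also takes all pair genes, the 15 nuclear protein-coding genes with the highest mean TPM, and the 10 genes past the threshold with a mean of at least 10 TPM and the largest deviation of 1 library from the other libraries. Some genes that the rule takes are not reported here.

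Other scalings of counts, filters of 50 counts or none, the second gene table, other pseudocounts and detection limits, FPKM, TPM without mitochondrial genes, and leaving out each library were the alternatives. DESeq2 gave alternative size factors and gene-wise dispersions. Removal of a trend on local GC content, and TPM over nuclear protein-coding genes, were added after seeing the data. Local GC content is the highest GC percent of any 200-base window of the gene's most abundant transcript, and the trend was a lowess curve (fraction 0.3) of each library's log2 deviation over genes with a mean count of at least 100. The window was picked after the deviation of library 3 had been compared with 14 measures over 9305 protein-coding genes, and after a search for short sequence motifs. Spearman rho was -0.49, -0.52, -0.53, -0.52, -0.48, -0.44 and -0.40 for windows of 50, 100, 200, 300, 500, 800 and 1200 bases. It was -0.44 and -0.46 for the first 200 and 500 bases, -0.12, -0.15 and -0.17 for the last 200, 500 and 1000, -0.31 for the whole transcript and -0.18 for its length. The lowess fraction was not varied. The chi-square of V genes was set against that of protein-coding genes of like count in both gene tables, with libraries scaled by the median ratio to the geometric mean. The limit in favour of separate animals could not be reached for T cell receptor V genes, which was seen only after the result. That test therefore cannot decide on separate animals.

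The comparison of libraries was run on simulated counts of 14877 genes. There 28% of genes changed by a factor of 1.25 in 1 library were called, 62% at 1.5, 80% at 2 and 96% at 4, while 16 of 14677 unchanged genes were called. A simulated coefficient of variation of 10% was estimated as 9.95%. These counts had Poisson noise alone or the same spread in every gene, unlike the real libraries. They therefore do not give the error rates in the real libraries. For the list levels, 1.5% of 200 random lists of 12 genes, drawn from 22028 protein-coding genes, lay in the top 2.5%. Tools were R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. With 1 group there was no comparison between conditions, no paired analysis and no other split of the samples.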

Results

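Messenger RNA was measured by polyA-selected RNA sequencing in mouse regulatory T cells described as having experienced inflammation, taken from a male adult animal of 16 weeks. Regulatory T cells are CD4 T cells that restrain immune responses and are defined by the transcription factor Foxp3. The strain name carries a Foxp3-linked GFP and diphtheria toxin receptor, a Cre recombinase that tamoxifen activates, driven from Cd4, and a tdTomato reporter. The series held 3 libraries in 1 group, which the labels call technical replicates 1, 2 and 3 of 1 biological replicate from 1 donor. They are called library 1, library 2 and library 3 here. No second condition was present, so levels were described within the group, and the only tests compared the 3 libraries with each other. Each SD is the spread between these 3 libraries, with n = 3 throughout, and does not measure variation between animals. The libraries held 20995859, 18455925 and 17535096 expected counts, and a count of 3 on a transcript of 1 kilobase, the floor used for genes at 0, stood for 0.23, 0.25 and 0.251 TPM, the unit of transcript abundance scaled for length and depth.

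The first question was which genes these cells expressed at high level. The most abundant nuclear protein-coding transcripts were those of Tmsb4x, which binds monomeric actin, at 14213 ± 1570 TPM (SD), and of the class I molecule H2-K1 at 9325 ± 2694 TPM. B2m, the light chain of class I molecules, followed at 7112 ± 1020 TPM. The 15 highest also held the class I gene H2-D1 (4445 ± 1912 TPM), the ribosomal protein gene Rps19 (4458 ± 667 TPM), and the elongation factor Eef1a1 (4323 ± 598 TPM). Actin genes and actin-binding genes stood among them as Actb (3820 ± 152 TPM), Cfl1 (3162 ± 307 TPM), Coro1a (2843 ± 71 TPM) and Tmsb10 (3960 ± 751 TPM). Shisa5, Ly6e, Ms4a4b and Ppia were also among the 15, with means of 4343, 3272, 2924 and 3851 TPM. At least 1 TPM in each library was reached by 12811 of the 55536 annotated genes, and by 10436 of the 22028 protein-coding genes. Genes with near-identical copies, such as Ppia, Actb and the class I genes, carry uncertain values where reads were shared between copies.

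The cells carried T cell and regulatory T cell transcripts together at high level. All 17 measured genes of the T cell identity list passed 100 TPM, led by the receptor constant genes Trbc2 (4125 ± 458 TPM), Trac (2933 ± 208 TPM) and Trbc1 (2178 ± 229 TPM) and by the kinase Lck (1401 ± 74.1 TPM). Cd4 stood at 266 ± 27.5 TPM and Cd8a at 1.02 ± 0.20 TPM, from 26, 31 and 21 counts. Each of the 12 genes of the Treg core list was detected in every library, and 10 of them passed 100 TPM. Izumo1r, the folate receptor 4 gene, reached 887 ± 121 TPM, Il2rb, a chain of the interleukin 2 receptor, 816 ± 101 TPM, Tnfrsf18, the gene of GITR, 589 ± 60.9 TPM, and Capg 432 ± 67.2 TPM. Il2ra, the gene of CD25, stood at 284 ± 15.4 TPM, Ikzf2, the gene of Helios, at 331 ± 58.3 TPM, and the inhibitory receptor gene Ctla4 at 268 ± 54.8 TPM. Foxp3 itself (chromosome X, 7573644 to 7595245, mm10) was measured at 77.6, 86.2 and 59.2 TPM, a mean of 74.4 ± 13.8. Foxp3 lay below Cd4, with a log2 ratio of TPM + 1 of -1.84 ± 0.42, and Trbc1 and Trbc2, whose reads are partly shared, did not differ by the rule for pairs (-0.92 ± 0.08). Among all protein-coding genes Foxp3 held rank 2349, while Ctla4 (chromosome 1, 60887000 to 60915832) held rank 530 and Il2ra (chromosome 2, 11642807 to 11693193) rank 485. The medians of both lists lay above those of nearly all of the 10000 random lists of protein-coding genes of the same size, at the 100th percentile to 3 decimals.

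**Figure D1:**
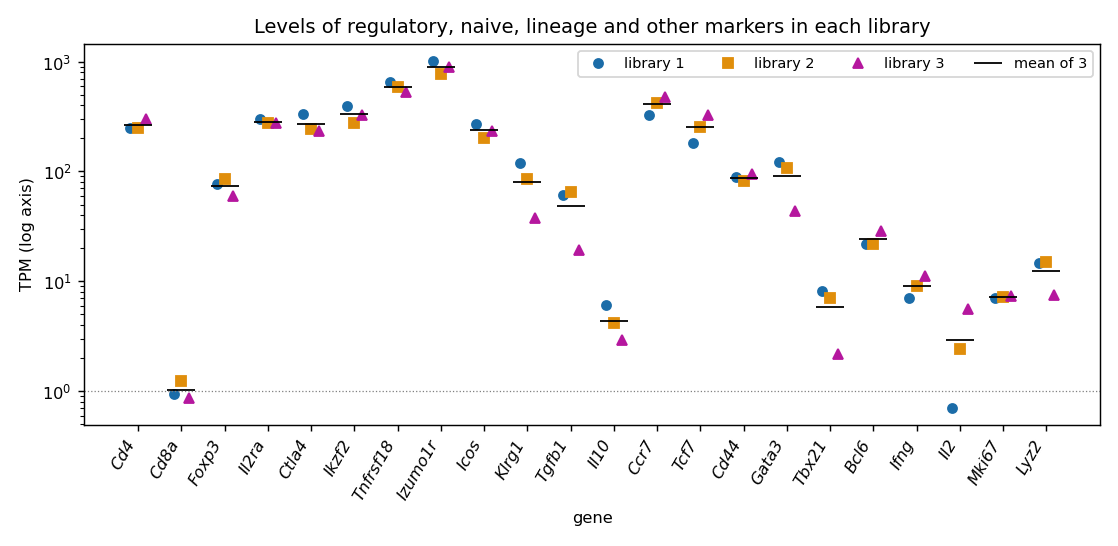
Level of marker genes in each of the 3 libraries, in TPM on a log axis, with the mean of the 3 libraries as a horizontal line and 1 TPM as the dotted line. Izumo1r (887 TPM) and Tnfrsf18 (589 TPM) were the highest of the genes drawn, and Gata3, Tgfb1 and Tbx21 were lower in library 3 than in the other libraries.

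Genes of activated or effector regulatory T cells were all detected. The 20 genes of that list had a median of 76.3 ± 19.6 TPM, at the 100th percentile of random lists, and 8 of them passed 100 TPM. The costimulatory receptor gene Tnfrsf4 reached 703 ± 109 TPM, Tnfrsf1b, the gene of TNF receptor 2, 297 ± 77.1 TPM, S100a6 280 ± 28.0 TPM and Icos 236 ± 34.5 TPM. Klrg1, a marker of terminally differentiated cells (chromosome 6, 122270596 to 122282882), was measured at 119, 84.6 and 37.4 TPM, a mean of 80.2 ± 40.8. Genes of suppressive mediators stood lower, with a median of 32.1 ± 15.8 TPM at the 99.2 percentile (62.9 against random lists of genes of at least 1 TPM) and 12 of 15 detected in each library. They were led by Lgals1 (409 ± 38.2 TPM), the ectoenzyme gene Nt5e (207 ± 39.0 TPM) and the inhibitory receptor genes Pdcd1 (200 ± 28.8 TPM) and Tigit (52.7 ± 14.8 TPM). Of the suppressive cytokines, Il10 (chromosome 1, 131019845 to 131024974) was measured at 6.03, 4.17 and 2.92 TPM, and Tgfb1 (chromosome 7, 25687002 to 25705077) at 60.7, 64.6 and 19.1 TPM. Ebi3, a chain of interleukin 35, was measured at 58.9, 41.1 and 37.4 TPM. Il12a, the other chain of interleukin 35, stayed between 0.07 and 0.27 TPM on 4 counts or fewer per library. Havcr2 was measured at 1.90, 2.16 and 0.84 TPM in libraries 1, 2 and 3, and Areg at 1.84, 2.08 and 0.43 TPM.

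Genes of naive or resting T cells were also abundant. All 14 members of that list were detected, 9 passed 100 TPM, and the median was 215 ± 21.2 TPM, at the 100th percentile. High members were the lymph node homing gene Ccr7 (408 ± 76.2 TPM), the transcription factor Foxp1 (288 ± 17.5 TPM) and the egress receptor S1pr1 (281 ± 19.2 TPM). Cd44, a gene of antigen-experienced T cells, stood at 87.9 ± 6.65 TPM. Ccr7 exceeded the skin-homing receptor gene Ccr8 by 2.37 ± 0.66 on the log2(TPM + 1) scale, and Tcf7, a transcription factor of resting cells, exceeded Prdm1, which is active in effector cells, by 3.58 ± 1.02. Lef1 and Id3 against Id2 did not differ by the rule set for pairs, at 0.50 ± 0.12 and 0.23 ± 0.38, nor did Il2ra against Il7r (0.23 ± 0.30) or Ctla4 against Cd28 (0.37 ± 0.40). Klf2, which drives S1pr1, was low at 12.4 ± 3.02 TPM and lay below Batf, a factor of effector regulatory T cells, with a log2 ratio of -4.10 ± 0.45. A pair was called different where the ratio had 1 sign in all libraries, exceeded 2 SD and exceeded 1 on the log2 scale, and 15 of 24 pairs met this. On counts of the second gene table, scaled for depth alone, the difference of Tcf7 over Prdm1 fell to 1.23 and was not called there. Lef1 over Id2 was called there at 1.56, and on counts of the first table scaled for depth alone at 1.41.

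Among the transcription factors of the helper lineages, Foxp3 exceeded Tbx21 by 3.60 ± 0.59 (log2), but not Gata3, against which the ratio was -0.18 ± 0.56. Gata3, the Th2 factor (chromosome 2, 9857078 to 9890034), was measured at 122, 108 and 43.3 TPM. Tbx21, the Th1 factor (chromosome 11, 97098071 to 97115331), was at 8.18, 7.05 and 2.16 TPM. Gata3 exceeded Tbx21 by 3.77 ± 0.03 in a pair of genes that both fell in library 3. Stat4 (188 ± 18.2 TPM), Zbtb7b (45.2 ± 8.86 TPM), Rora (38.2 ± 15.3 TPM) and Bcl6, the factor of follicular helper cells (24.0 ± 4.04 TPM), were detected in every library, while Eomes and Hlx were not. The list's median stood at the 96.4 percentile, and at 44.1 against random lists of genes of at least 1 TPM. Ikzf2 exceeded its relative Ikzf4 by 1.54 ± 0.14. On counts scaled for depth alone, the first gene table gave 1.44 and the second -0.48.

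Transcripts of effector cytokines were few. Of 13 such genes, 4 reached 1 TPM in each library: Tnf (39.9 ± 1.95 TPM), Il21 (11.3 ± 6.25 TPM), Ifng (9.16 ± 2.08 TPM) and Il4 (7.48 ± 4.88 TPM). Il17a had no count in any library, which allows up to 0.22 TPM by counting error. Il2, which regulatory T cells bind and seldom make, was measured at 0.71, 2.43 and 5.64 TPM, from 10, 32 and 74 counts. Il10 and Il2 were not told apart by the pair rule, with a log2 ratio of 0.62 ± 1.40. The median of the cytokine list lay at the 25.8 percentile of random lists, and at 0 against random lists of genes of at least 1 TPM. Tgfb1 exceeded Il10 by 3.05 ± 0.66.

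Receptor genes for homing and for cytokines were broadly expressed. All 19 homing receptor genes were detected, with Selplg (761 ± 49.7 TPM), the gut-homing integrin gene Itgb7 (679 ± 205 TPM) and Itga4 (288 ± 26.9 TPM) beside Ccr7. Cxcr3 (195 ± 23.8 TPM) and Cxcr5 (120 ± 25.8 TPM) did not differ by the pair rule, at 0.71 ± 0.14, and Ccr4 (33.5 ± 5.35 TPM) stood above Cxcr4 (16.4 ± 1.64 TPM) by less than the rule asks, at a log2 ratio of Cxcr4 to Ccr4 of -0.98 ± 0.36, a pair that was called in 4 of the alternatives, at -1.01 to -1.26. Of 19 cytokine receptor genes 17 were detected, led by the common gamma chain gene Il2rg (1360 ± 99.9 TPM), Ifngr1 (372 ± 96.8 TPM), Il27ra (345 ± 10.4 TPM) and Il21r (306 ± 30.8 TPM), and the 2 others were Il12rb2 and Il1r1. S1pr1 exceeded Klrg1 by 1.94 ± 0.94, a call that was lost without library 2. Both lists had medians at the 100th percentile.

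Genes of survival, growth and metabolism were then listed. The 10 survival genes had their median at the 99.9 percentile (92.2 against random lists of genes of at least 1 TPM), with Cflar (129 ± 6.63 TPM), Bcl2 (115 ± 21.3 TPM), Fas (86.3 ± 12.8 TPM) and Bcl2a1d (56.5 ± 9.37 TPM) highest, and Bcl2 exceeded Mcl1 by 1.68 ± 0.35. The 15 proliferation genes lay at the 93.9 percentile, and at 9.72 against random lists of genes of at least 1 TPM, with Pcna at 141 ± 21.2 TPM, Mcm2 at 60.5 ± 2.48 TPM, Mcm5 at 52.4 ± 5.19 TPM and Tyms at 38.4 ± 11.0 TPM. Mki67, a gene of dividing cells, was measured at 7.18 ± 0.11 TPM and lay below the cell cycle inhibitor gene Cdkn1b (40.3 ± 3.74 TPM), with a log2 ratio of -2.33 ± 0.11. On counts scaled for depth and not for length, that ratio was -0.94 and was not called, and in the second gene table it was 0.27, with the sign reversed. Interferon response genes reached the 100th percentile, with Ifi47 (403 ± 56.1 TPM), Igtp (372 ± 36.8 TPM) and Irgm1 (137 ± 13.9 TPM) among the highest. Immediate early genes lay at the 95.2 percentile (14.8 against random lists of genes of at least 1 TPM) and NF-kB pathway genes at the 99.98 percentile (96.4), the first led by Junb (316 ± 200 TPM), Zfp36, Myc and Ier2, the second by Nfkbia (565 ± 234 TPM), Traf1, Rela and Birc3. Of the immediate early genes, Fosb (0.59 ± 0.07 TPM) and Atf3 (0.14 ± 0.09 TPM) stayed under 1 TPM. Glycolysis genes such as Ldha (982 ± 83.1 TPM), Eno1, Pkm and Aldoa stood at the 100th percentile, and fatty acid oxidation genes such as Hadhb (188 ± 13.3 TPM), Acaa2, Acadvl and Hadha at the 99.9 percentile (95.6 against random lists of genes of at least 1 TPM). Chromatin genes lay at the 98.7 percentile (57.6 against random lists of genes of at least 1 TPM) with Dnmt1 (89.4 ± 4.91 TPM), Eed, Kdm6a and Tet2 highest, and Dnmt1 exceeded Dnmt3a by 1.76 ± 0.34. Housekeeping genes, with B2m, Ppia, Actb and Rplp0 at the top, stood at the 100th percentile. In all, 14 of the 18 lists on the cells themselves lay in the top 2.5% of random lists, and 9 did when the random lists were drawn only from genes of at least 1 TPM.

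**Figure D2:**
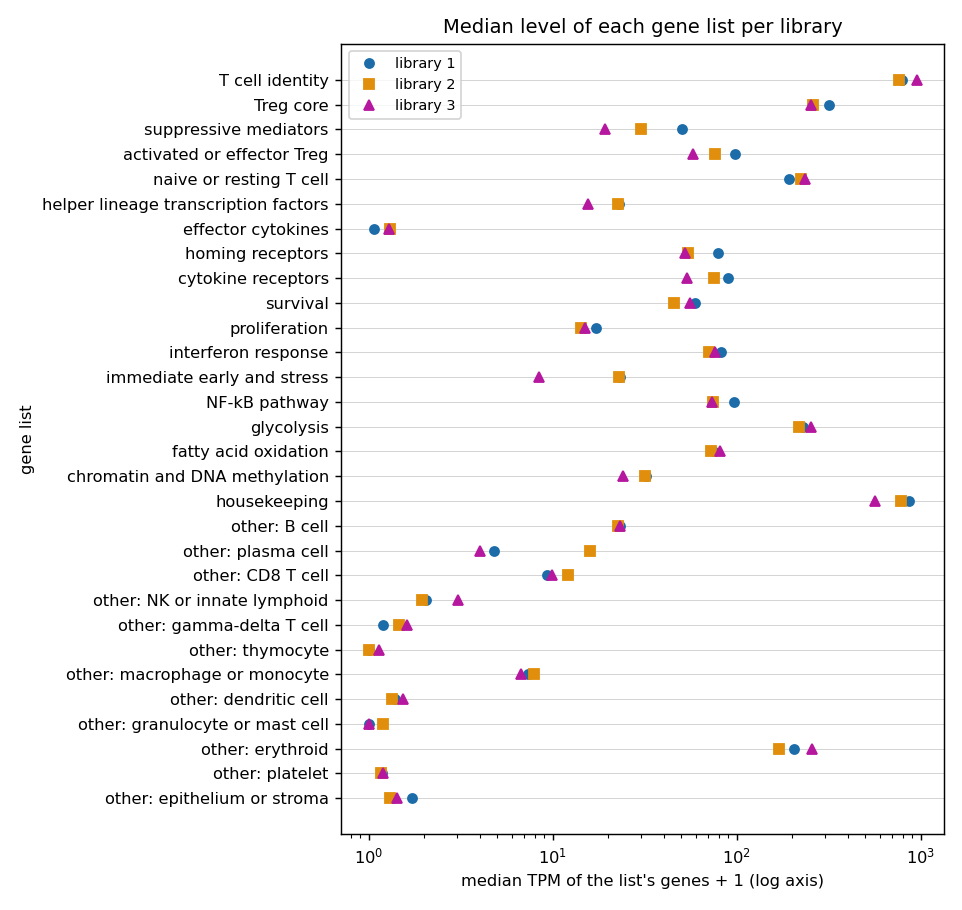
Median TPM of each gene list plus 1, on a log axis, in each of the 3 libraries. Averaged over the libraries the T cell identity list had the highest median (837 ± 102 TPM), while in libraries 1 and 2 the housekeeping list was higher (863 and 776 TPM against 793 and 764), and among lists of other cell types the erythroid list (209 ± 43.7 TPM) stood apart from the rest, which reached 21.9 TPM at most.

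Markers of other cell types were looked for because a sort can carry neighbouring cells. The erythroid list had the highest median of them: Hbb-bs stood at 494 ± 129 TPM, Hba-a2 at 492 ± 109 TPM, Hba-a1 at 312 ± 70 TPM and Hbb-bt at 107 ± 18.2 TPM. The list's median was 24.9 ± 2.51% of that of the T cell identity list. It lay at the 99.99 percentile of random lists, and at 99.8 against random lists of genes of at least 1 TPM. A high percentile was therefore not particular to lists of the cells themselves. B cell genes came next, at 2.64 ± 0.29% and the 96.7 percentile (36.6 against random lists of genes of at least 1 TPM), with 12 of 13 detected. Among them Ighm reached 1486 ± 206 TPM, Cd74 346 ± 7.69 TPM, Igkc 237 ± 65 TPM and Cd79b 45.1 ± 0.81 TPM. The CD8 T cell list, of Cd8b1 (17.9 ± 2.79 TPM) and Cd8a, stood at 1.15 ± 0.28%, the plasma cell list at 0.92 ± 0.91% (0.48, 1.96 and 0.32% in libraries 1, 2 and 3) and the macrophage list at 0.77 ± 0.15%. The plasma cell list was led by Xbp1 (37.0 ± 22.0 TPM), Igha (3.77, 92.8 and 1.62 TPM), Irf4 (21.8 ± 1.45 TPM), which effector regulatory T cells also express, and Jchain (11.7 ± 2.90 TPM). Macrophage genes held Ctss (328 ± 35.8 TPM) and Cst3 (139 ± 4.78 TPM) at high level, and Csf1r (14.2 ± 1.93 TPM) and Lyz2 (14.8, 15 and 7.45 TPM) at low level. The NK cell list (0.16 ± 0.05%, led by Nkg7 at 113 ± 19.5 TPM), the epithelial and stromal list (0.06 ± 0.03%, led by Pecam1), the gamma-delta T cell list (0.05 ± 0.02%), the dendritic cell list (0.05 ± 0.01%), the platelet list (0.02%) and the granulocyte list (0.01%) were lower. In these lists Tyrobp (13.2 ± 1.28 TPM), Tcrg-C1 (7.06 ± 0.23 TPM), Klrb1c (4.23 ± 0.99 TPM), Epcam (3.02 ± 1.93 TPM), Trdc (2.88 ± 0.52 TPM), Zbtb46 (1.42 ± 0.20 TPM), Gzma (1.35 ± 1.29 TPM) and Itga2b (1.30 ± 0.18 TPM) had means over 1 TPM. Means under 1 TPM were found for Zbtb16, Trdv4, Siglech, Xcr1, Itgax, S100a9, Cpa3, Retnlg, S100a8, Gp9, Ppbp, Pf4, Col1a1 and Col1a2. The thymocyte list was lowest by its median, although Themis, which mature T cells also express, was measured at 32.7, 62.7 and 84.1 TPM, beside Dntt (1.62 ± 0.68 TPM), Ptcra (0.05 ± 0.08 TPM) and Rag1 (0.01 ± 0.02 TPM). Y-linked Ddx3y (102 ± 12.8 TPM), Eif2s3y (120 ± 6.47 TPM), Kdm5d (47.4 ± 5.95 TPM) and Uty (45.6 ± 6.64 TPM) were expressed, and Xist reached 0.22 TPM and Tsix 0.17 TPM at most, in a list whose median lay at the 98.4 percentile (81.8 against random lists of genes of at least 1 TPM).

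The leading isoform of 20 chosen genes took a median of 69.0 ± 2.89% of each gene's TPM. A single transcript held 99.1 ± 0.43% of Ctla4, 96.5 ± 0.72% of Tcf7 and 92.6 ± 2.00% of Cd4. Foxp3 was split, with 56.4 ± 4.33% assigned to Foxp3-207, annotated as a nonsense-mediated decay transcript of 1557 bases, and 22.1 ± 1.15% to the coding Foxp3-206. For Ikzf2, 63.8 ± 3.96% went to Ikzf2-205, a retained intron transcript of 1905 bases, but that transcript took only 35.5% of the gene's expected counts, since TPM divides by length. Icos was divided between a transcript of 3241 bases (54.8 ± 1.60%) and one of 810 bases (45.3 ± 1.60%). For Ptprc, the gene of CD45, the leading Ptprc-203 took 37.3 ± 1.60%. Shares of overlapping transcripts are model estimates from short single reads, and in expected counts the median leading share was 79.6%.

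The 3 libraries were compared gene by gene to see whether they differed by more than counting. Of 14877 genes with a mean count of at least 10, 9501 differed between libraries (Pearson chi-square test against Poisson sampling with edgeR TMM scaling, Benjamini-Hochberg adjusted p under 0.05). Among the members of the gene lists at a mean of at least 1 TPM, all 12 Treg core genes, all 14 naive genes and all 17 T cell identity genes differed, and the same 12, 14 and 17 when adjusted over the list alone. For the 20 activated or effector genes, 18 differed, and 19 adjusted over the list alone. Such calls depend on depth, since 63.9% of all tested genes differed and 76.0% of those with a mean count of at least 50. Genes with many counts were called at small differences, as was Cd5 with a coefficient of variation of 2.47% in TPM. The calls are therefore not particular to these lists. The spread beyond counting was a coefficient of variation of 27.8%, and of 13.0% as the median of DESeq2's gene-wise dispersions. Without library 3, 4489 of 14868 genes differed and the coefficient was 13.3%. Log2 levels of 9995 genes with a mean count of at least 100 differed by more than 1 for 0.61% of genes between libraries 1 and 2, for 15.5% between libraries 1 and 3, and for 14.5% between libraries 2 and 3. These tests compare 3 libraries of 1 biological replicate, not conditions, and n = 3 values cannot give an exact two-sided sign-flip p under 0.25.

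Library 3 held less of many genes. Among the Treg core genes 7 of 12 were lowest there, and among the activated or effector genes 10 of 20. By their medians, though, both lists stood apart in library 1, at 0.32 and 0.33 (log2) above the mean of the other libraries. They deviated by -0.16 and -0.16 in library 2, and by -0.18 and -0.17 in library 3. Other lists held more in library 3, where 14 of 17 T cell identity genes and 8 of 14 naive genes were highest. The median deviation of the T cell identity list there was 0.21, and 0.11 with the local GC trend removed. For the naive list it was 0.14 and 0.18, but that list deviated more in library 1, at -0.33. Junb was measured at 466, 392 and 89.4 TPM in libraries 1, 2 and 3, the immediate early gene Ier2 at 139, 147 and 31.3 TPM, and Nfkbia, an inhibitor of NF-kB, at 734, 664 and 298 TPM. H2-D1 stood at 5832, 5239 and 2264 TPM, and Xbp1 at 52.7, 46.5 and 12 TPM. Itgb7, at 803, 791 and 442 TPM, had 17215, 14444 and 4515 expected counts, as its estimated mean transcript length also differed between libraries. Tgfb1, Gata3 and Tbx21 deviated in library 3 from the mean of the other libraries by -1.71, -1.34 and -1.79 on the log2 scale. Of 9305 protein-coding genes with a mean count of at least 100, 1411 fell to under 1/2 of the mean of the other libraries in library 3, against 25 in library 1 and 6 in library 2. The deviation varied with the GC content of the richest 200-base window of the transcript, a measure picked from 14 after their correlations with it were seen, and it did not fall steadily with GC content. In 1390 genes whose richest 200-base window was 70 to 75% GC the median deviation of library 3 was -0.92, in 879 genes of 75 to 80% it was -0.89, in 2231 genes of 60 to 65% it was 0.08, and in 348 genes over 80% it was -0.05. Of the genes of 70 to 80% GC 45.4% fell to under 1/2 in library 3, of those over 80% 8.33%, and of those under 65% 3.34%. The windows of Junb, Tgfb1 and Gata3 held 71.5%, 78.5% and 74% GC, and those of Foxp3 and Klrg1, at deviations of -0.39 and -1.40, held 65% and 55%.

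**Figure D3:**
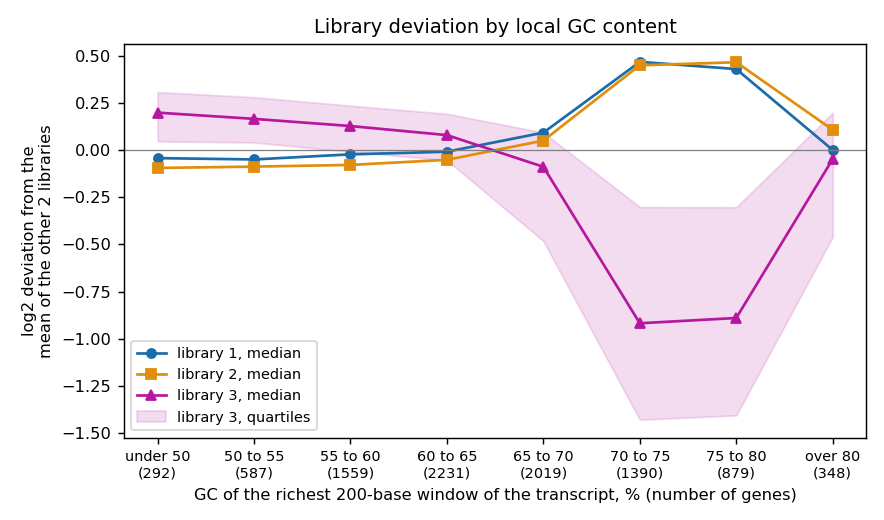
Median log2 deviation of each library from the mean of the other libraries (y axis) for 9305 protein-coding genes grouped by the GC content of the richest 200-base window of their most abundant transcript (x axis, with the number of genes). The shaded band spans the quartiles of library 3, whose median was -0.92 at 70 to 75% GC and -0.05 over 80%.

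The 10 genes with the largest deviation of 1 library, among those past the threshold with a mean of at least 10 TPM, were mostly immunoglobulin variable genes, pseudogenes and short RNAs. Igkv8-27 had 2, 0 and 199 counts in libraries 1, 2 and 3, Igkv5-39 127, 0 and 74 counts, and Igkv8-21 4, 127 and 2 counts. Igha, the constant gene of IgA antibodies, had 59, 1176 and 31 counts, the ribosomal pseudogene Rps3a3 20, 4267 and 37 counts, and Gm2436 0, 127 and 155 counts. Gm42845, AL731706.2, Gm47308 and Gm44390 held 58, 41, 22 and 43 counts at most in a library. Reads of pseudogenes and of variable genes are shared with near-identical copies, so their counts are uncertain.

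The second gene table held 22195 genes that matched the first table and 262 that did not. Ranks of genes were close in both tables, with a mean Spearman rho of 0.944 ± 0.004 over the libraries, where genes are not independent replicates. Of 320 list genes in both tables, 264 had at least 10 counts in each library in the second table and 275 in the first. Abundant genes held far fewer counts in the second table: Lck had 3243, 3240 and 3234 there, against 31235, 26342 and 28117 expected counts. For 3197 genes with 0.1 to 0.3 expected counts per exonic base the second table held a median of 50.2% of the expected counts, and for 52 genes with over 10 per base 2.16%. The pairs Ikzf2 over Ikzf4 and Mki67 under Cdkn1b turned to -0.48 and 0.27 (log2) in that table, and the uncalled pairs Il2ra over Il7r and Id3 over Id2 to -0.47 and -0.09. These ratios used counts scaled for depth and not for length, from a table that holds too few counts of abundant genes. So scaled, the first table gave 1.44 for Ikzf2 over Ikzf4 and -0.94 for Mki67 over Cdkn1b.

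**Figure D4:**
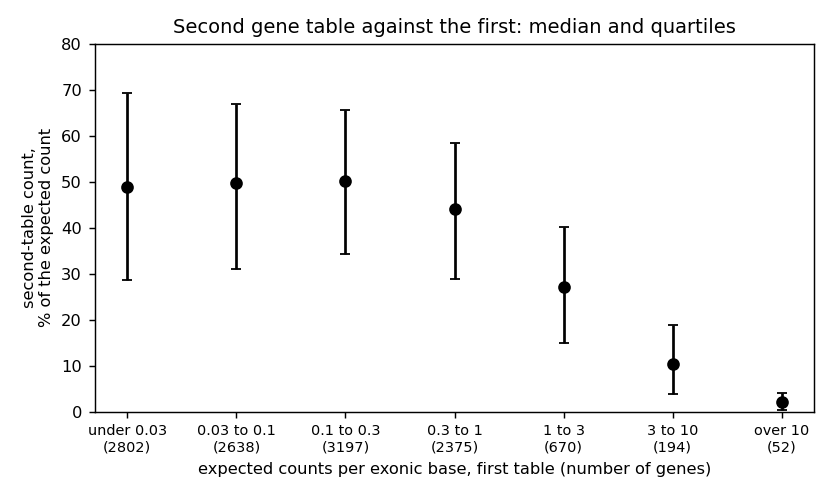
Count in the second gene table as a percent of the expected count of the first (y axis, median with quartiles as bars), for genes grouped by expected counts per exonic base (x axis, with the number of genes). The median was 50.2% at 0.1 to 0.3 counts per base and 2.16% over 10.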

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

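The tests on T cell receptor V genes, sex-linked genes, other cell types and gene length were set before the result was seen. Those on immunoglobulin V genes, of which 3 with large differences had been seen, on local GC content, with its window size, GC classes and bounds, and those on the levelling of the second table were chosen only after it. With 1 group, no biological explanation was tested in the sense of a difference between conditions, and separate animals, different or other cells and a female animal were weighed as a wrong label or a mixed sample.

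Entries outside the comparisons held counts above the 3 that a count of 0 allows. The sequencing control phiX174 had 51737, 51732 and 38384 expected counts in libraries 1, 2 and 3, and the tRNA entries together had 1363, 1845 and 1912.

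The first pattern is that 9501 of 14877 genes differed between libraries called technical replicates, 4489 without library 3. That the libraries hold different cells, not aliquots of 1 RNA, may be a part of it, but the test made cannot decide this. Immunoglobulin V genes, each carried by few cells, had a chi-square 19.8 times that of genes of like count (19 genes, bootstrap interval 16.2 to 29.8). In the second table it was 25.6 times. The class was chosen after 3 of its genes were seen to differ, so a high ratio was likely beforehand. Reads shared with near-identical copies could also raise it, and the interval treats the genes as independent. The test says nothing on the other genes. T cell receptor V genes differed between libraries no more than genes of like count did, which cannot decide on separate animals. The share of T cell receptor V genes past the threshold was 0.840 of that of genes of like count (bootstrap interval 0.670 to 1.003), at 42.1% of 121 against 50.2%. By chi-square, a measure added after that result was seen, the ratio was 0.825 (0.491 to 0.954). In the second table it was 0.578 (0.378 to 0.838). The share could reach only 1.99 where 2 was asked in favour, and animals alike in V gene use would not be seen. Xist at 0.220 TPM at most argues against a female animal. A different share of other cells in 1 library may account for a few genes: of lists with at least 3 genes compared, the plasma cell list deviated most, by 0.864 (log2) in library 2, but that median is the value of Xbp1, of which library 3 held little, and the 5 erythroid genes, all highest in library 3 (median 0.51), are the clearer case. A trend with gene length stays open, since rho with effective length across genes was -0.148 in library 3, between the bounds set beforehand.

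The second pattern is that 1411 of 9305 genes fell to under 1/2 in library 3. Loss of transcripts with a stretch of high GC content is a candidate explanation: such falls were 13.6 times as frequent in genes with a window of 70 to 80% GC as in genes under 65%, and 12.1 times with genes over 80% included. The difference between libraries did not grow steadily with GC content, since the genes over 80% deviated by only -0.05. As a ratio between libraries, the deviation cannot show a loss that all libraries share. The removed trend does not account for all of the falls, because 35.9% of the genes stayed under 1/2 without it. That curve follows the centre of genes of like GC content and leaves the spread around it, which ran from -1.43 to -0.30 (quartiles) at 70 to 75%. The test therefore cannot say how much of the falls GC content accounts for. The first table's quantification alone is argued against, since the second table's counts showed the same difference between these GC classes, -1.13 (log2). Klrg1 fell too, with a window of 55% GC.

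The third pattern is that counts of the second table level off for abundant genes. Counting reads at the same position once is a candidate explanation, since in 46 genes with over 10 expected counts per exonic base the spread between libraries was 0.331 of that of Poisson counting. Leaving out a fixed share of each gene's reads, as for reads that map to several places, is argued against by the slope of the library ratios between the tables, 0.032, where 1 would be kept. How that table was counted is not given in the sources used here.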

How the results depend on the processing

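The removal of the GC trend and the TPM over nuclear protein-coding genes were chosen after seeing the data. Of the main summaries, 44 settings gave a value within the limits set for the same result and 8 did not. These limits were wide, so the tally does not measure robustness. For example, 7674 differing genes without library 1 counted as the same result as 9501. For the coefficient of variation the limit was the SD of the values with 1 library left out, so 32.1 and 33.9% counted as the same as 27.8%. The count of differing genes was 6222 in the second gene table, which tests fewer genes, and between 4489 and 8029 when 1 library was left out, lowest without library 3. The coefficient of variation was 13.0% as the median of DESeq2's gene-wise dispersions and 13.3 to 33.9% with 1 library left out, again lowest without library 3. With random lists from genes of at least 1 TPM, 9 lists lay in the top 2.5%. The median leading isoform share was 79.6% in expected counts, the erythroid ratio 20.9% from list means, and rho between both gene tables was 0.867 over genes of at least 1 TPM. Of the called pairs, Ikzf2 over Ikzf4 (-0.483) and Mki67 over Cdkn1b (0.268) changed sign in the second table, as did the uncalled Il2ra over Il7r (-0.473) and Id3 over Id2 (-0.089). Those ratios used counts scaled for depth alone. Where no construction above shows a cause, the cause was not tested. For single lists, pairs and detection counts, 446 values were within the limits, 44 moved, 4 lost and 6 gained a call, and the 2 called pairs above changed sign and lost theirs. Removing the GC trend left 8716 genes differing. Depth limits genes with few counts, such as Il2 with 10 in library 1. No paired analysis was possible because the series holds 1 group.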

Other observations

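The list shifts were examined only after the libraries were seen to differ. On normalised counts, libraries 1 and 2 differed in many of the lists, not in those of regulatory and naive T cells alone. Of the 12 Treg core genes, all but Foxp3 were higher in library 1 than in library 2, with a median log2 difference of 0.30, at the 100th percentile of 10000 random lists matched on expression. Of the 20 activated or effector genes 17 were higher in library 1 (median 0.29), and all 15 proliferation genes were (0.30), both at the 100th percentile, although in TPM Mki67 (7.07 and 7.20), Ccnb1 (7.96 and 8.70) and Cdk1 (12.51 and 12.52) were not higher in library 1. Of the 14 naive genes only 2 were higher in library 1, with a median of -0.34, at percentile 0. Ctla4, for example, was at 331 and 241 TPM in libraries 1 and 2, and Tcf7 at 181 and 251 TPM. Interferon response genes were higher in library 1 in 13 of 14 cases, with a median of 0.23. Suppressive mediators (0.34), cytokine receptors (0.18), survival genes (0.19) and erythroid genes (0.31, 5 of 5) were higher in library 1 by their medians too, all past the 99th percentile. Lower in library 1 by their medians were effector cytokines (-0.39, percentile 2.45) and B cell genes (-0.14). For the B cell list 6 of 12 genes were higher in library 1, and its percentile was 0.15 over 9 protein-coding genes. These percentiles describe 3 libraries of 1 biological replicate and are no test between conditions.

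Of 13 effector cytokine genes 5 could be compared, and 4 of these differed between libraries by the test. All 5 were highest in library 3, with a median deviation of 1.29 (log2), among them Il2 (0.71, 2.43 and 5.64 TPM), Il4 (3.35, 6.23 and 12.9 TPM) and Il21 (9.52, 6.09 and 18.2 TPM). Erythroid genes were also highest in library 3, in 5 of 5 cases, with a median deviation of 0.51, and Hbb-bs stood at 492, 366 and 624 TPM. Of 8 NK or innate lymphoid genes, the 5 that could be compared were highest in library 3 as well, with a median deviation of 0.49, and 4 of them differed by the test. Helper lineage factors deviated by -0.83 in library 3 and by -0.05 with the local GC trend removed. Immediate early genes deviated by -0.73 and, with that trend removed, by -0.55.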
